A study of Mus musculus with 21 samples.

How the data were processed

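The libraries came from RNA of the left-ventricular free wall of 21 mice, 1 library per mouse, per the labels' protocols. RNA of 1.5 µg was alkylated in 12 mM iodoacetamide, and libraries were made with a QuantSeq 3′ kit that keeps strand and sequenced as single-end reads of 100 bases, per the labels. Tamoxifen was given at 6 to 8 weeks of age on 4 days, per the labels. The deposited table has 1 row for each of 208307 3′ UTR intervals and library, and its column layout is that of SlamDunk, per the file headers. The genome build is mm39, per the submitters' processing notes. The aligner settings, the annotation release, any filter on known sequence variants and the number of conversions that marks a read are not given in the sources used here.

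The deposited values used are counts, per the file headers: reads on an interval, reads with a T>C conversion, multimapped reads, read bases over reference T positions, and T>C conversions over them. The table also holds a CPM column, which the authors' tool computed. That column was treated as a score, per the file headers, and used only to find the library total behind it. No read was re-aligned. T>C reads never exceeded reads on an interval in any row, and 0 columns of samples outside the labels were present.

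Intervals of 1 strand that overlap were reduced to the 1 with the most reads, and separate intervals that share a transcript ID were summed, which gave 46278 loci. A locus is named by the transcript ID and the position of its most read interval. Intervals that adjoin without overlap stay separate and can hold the same reads. The supplied reference table (GRCm38.p6) matched 0 of the transcript IDs, so no gene name is given. For the same reason the 25 gene lists with 482 members fixed in advance, which included the cell type markers, the level of Lmna and the exclusion of loci within a set distance of Lmna were not run. In their place chromosome 3, to which the reference table assigns Lmna, was left out as a whole. The loci printed by ID are 2 that rose and 2 that fell; the others are given by position.

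All tests used an adjusted p of 0.05 (Benjamini-Hochberg). All reads were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with its minimum count of 10, TMM, glmQLFit and glmQLFTest) in 1 fit of the 21 libraries with group means and sex. T>C reads were tested the same way in the 14 mice with Uprt and, separately, in the 7 without, with Lmna genotype and sex as terms. The T>C share of a locus was tested in edgeR on a table with converted and unconverted reads of each library, with an effect for each library and read type by group and by sex. The value after a log2 fold change is its standard error, taken as the fold change over the square root of the quasi-likelihood F statistic. CPM values use TMM-scaled library sizes. Library-level percentages were compared by two-sided exact permutation tests. Enrichment used Fisher's exact test and a Mantel-Haenszel odds ratio over 10 strata of mean CPM in all 21 libraries. The score of a library is the mean log2 CPM of the loci called higher minus that of the loci called lower, with 0.5 added to each CPM.

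Named loci were those past the threshold with a mean of at least 1 CPM and the largest change in each direction, a rule fixed before the data were examined with 10 per direction. The number was lowered to 2 per direction after the files showed IDs that could not be paired with names, and unnamed gene models could not be left out. For Uprt against none, in all reads and in the T>C share, it was 1 per direction. The 3 T>C loci lower in Lmna F/F without a call in all reads, and the loci on chromosomes 2, 11 and 13 described by library, follow from calls and were described after their values were seen.

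The alternatives chosen before the data were examined were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in place of TMM, no low-count filter, no sex term, the most read interval alone, 1 sex alone, fewer groups in the fit, a quasi-binomial model squeezed with limma 3.58.1, Uprt-labelled loci alone, and each library left out in turn. Those added after seeing the data were library size alone, the exclusion of chromosome 3, of mitochondrial loci with the most abundant nuclear locus, and of loci whose T>C share reaches 20% (with at least 20 reads) in a mouse without Uprt, mitochondrial or nuclear loci alone, and the omission of Lmna F/F no Uprt replicates 1 and 2 together.

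Each test was first tested on simulated counts drawn from the real means and library sizes, with 200 loci changed by 1 on the log2 scale. The spread was taken from the data as 1 value per locus for all groups of the fit. The changed loci were picked among those with a mean of at least 1 CPM, or for shares above a minimum mean of T>C reads. Recovery at loci with fewer reads was therefore not tested. Recovered were 73.5% for all reads between Lmna genotypes with Uprt (20035 loci), 41.5% without Uprt (19950 loci), 22.0% for the interaction with Uprt (20035 loci), 82.0% for Uprt against none (19983 loci) and 84.0% for females against males (19971 loci). For T>C reads 26.5% were recovered with Uprt (9244 loci) and 0 of 200 without Uprt (7117 loci) or for the interaction with sex (9291 loci). For the T>C share 89.0% were recovered for Uprt against none (10813 loci) and 88.0% between Lmna genotypes (9713 loci). Simulated shares carried a beta-binomial overdispersion set at 0.002, which was not estimated from the data and does not model sequence variants between mice.

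Depth was 25947355 to 50951631 reads on loci per library. Mitochondrial loci took 23.7% to 33.6% of reads, and multimapped reads were 9.31% to 11.0%. Pairs of libraries of 1 group differed far beyond counting noise, with a chi-square per degree of freedom of at least 21.2, so no library was counted as a repeat of another. Reads carry no molecular identifiers in the table, so any limit from counts covers counting error only. CPM stands for counts per 1e+06 reads on loci. The labels give 1 pool for all libraries and no batch. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the tables and the permutation tests.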

Results

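Newly made RNA was measured in adult mouse heart by SLAM-IT-seq, in which a uracil analogue, 4-thiouracil, is built into RNA mainly in cells that carry the enzyme uracil phosphoribosyltransferase (Uprt). All 21 mice had received tamoxifen, which activates the Cre recombinase driven by the cardiomyocyte promoter of Myh6, and were given 4-thiouracil 2 weeks later. Hearts were taken 6 hours after that dose. Iodoacetamide then makes the built-in analogue read as a T>C conversion, so a read with such a conversion marks RNA that was made during labelling or a background error. The mice fell into 4 groups by the Lmna gene, which encodes lamin A/C of the nuclear envelope, and by the Uprt transgene. There were 8 Lmna +/+ mice with Uprt (4 females, 4 males), 6 Lmna F/F mice with Uprt (4 females, 2 males), 4 Lmna F/F mice without Uprt (2 females, 2 males) and 3 Lmna +/+ mice without Uprt, all male. F stands for the floxed allele that the recombinase deletes. Libraries held 25947355 to 50951631 reads on 3′ UTR loci, and 1124258 to 2414184 of these carried a T>C conversion. The 3′ UTR intervals carry Ensembl transcript IDs that the files do not pair with gene names, so loci are given by ID or by position on mm39, and the level of Lmna itself could not be looked up.

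The first comparison asked whether the transgene raised the share of reads with a T>C conversion. In Lmna +/+ hearts 4.92% ± 0.451 of reads carried a conversion with Uprt (SD, n = 8), against 3.57% ± 0.423 without it (SD, n = 3). In Lmna F/F hearts the share was 5.07% ± 0.272 with Uprt (SD, n = 6) and 3.61% ± 0.331 without (SD, n = 4). On nuclear loci alone the shares were 5.01% ± 0.453 against 3.15% ± 0.417 in Lmna +/+ and 5.30% ± 0.330 against 3.53% ± 0.307 in Lmna F/F. The 14 mice with Uprt all lay above the 7 without it on nuclear loci. On mitochondrial loci the difference was 0.00276 percentage points in Lmna +/+ (two-sided exact permutation p = 0.982, n = 8 and 3) and 0.661 points in Lmna F/F (exact permutation p = 0.114, n = 6 and 4).

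Over all loci the difference of 1.35 percentage points in Lmna +/+ had a two-sided exact permutation p of 0.0121, the smallest that 8 against 3 mice allow (adjusted p = 0.0242 over 4 comparisons). The difference of 1.46 points in Lmna F/F had an exact permutation p of 0.00952, the smallest for 6 against 4 mice (adjusted p = 0.0242). No difference between Lmna genotypes was called, with Uprt (exact permutation p = 0.487, n = 6 and 8) or without (exact permutation p = 0.857, n = 4 and 3, where no value below 0.0571 is possible). With Uprt the difference of 0.153 points ranged from 0.0756 to 0.297 with 1 library left out, the highest without Lmna +/+ Uprt replicate 3. Among Lmna +/+ males alone the transgene difference was 1.21 points with an exact permutation p of 0.0571, the smallest that 4 against 3 allow.

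**Figure D1:**
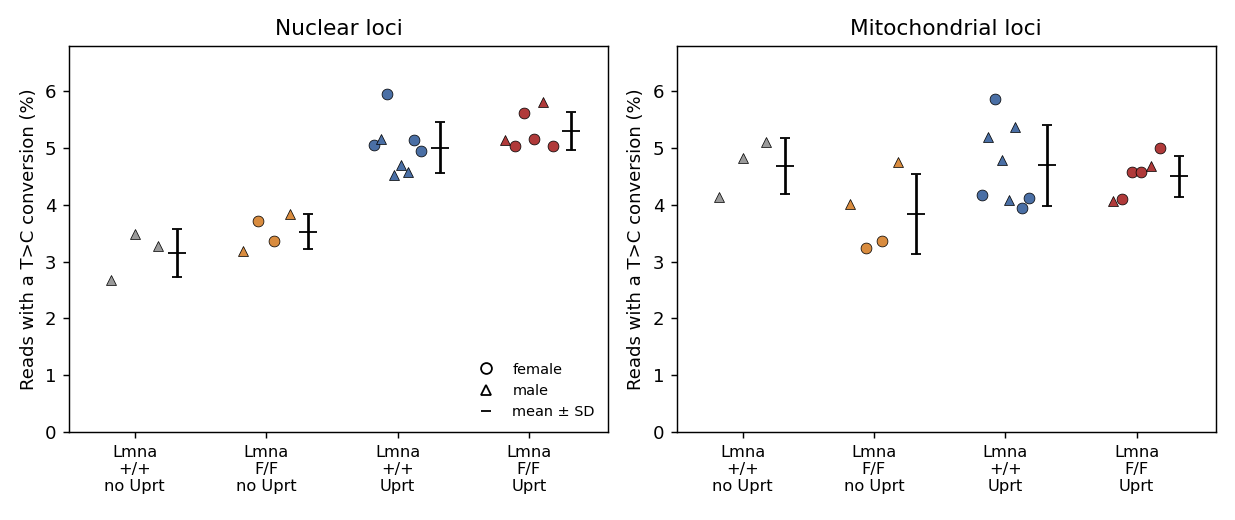
Percent of reads with a T>C conversion in each library, on nuclear loci (left) and mitochondrial loci (right), by Lmna genotype and Uprt; circles are females, triangles males, and bars the mean ± SD. On nuclear loci all 14 mice with Uprt lie at 4.52% or above, and the 7 without it lie at 3.85% or below.

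Most loci with enough reads took part in this rise. The odds of a T>C read were higher with Uprt at 7038 of 11938 loci tested (59.0%) and lower at 25, by edgeR's quasi-likelihood test on converted and unconverted reads at an adjusted p under 0.05. At the loci called higher, the median log2 odds ratio was 1.60, with quartiles of 1.13 and 2.10. The loci called higher include 12 of the 14 mitochondrial loci tested, with a median log2 odds ratio of 0.67 over the 14. The largest rise was at a chromosome 10 locus from 111134540 to 111137586, where no read of the 7 mice without Uprt carried a conversion, against 11.6% ± 6.73 in Lmna +/+ with Uprt (SD, n = 8) and 11.4% ± 13.3 in Lmna F/F with Uprt (SD, n = 6). A chromosome 19 locus from 21914744 to 21915745 had a log2 odds ratio of -2.50 ± 0.69 (SE, edgeR adjusted p = 0.00381), and was not called in the quasi-binomial model (-1.61) or in Lmna +/+ alone (-2.30). Its T>C share differed widely between mice without Uprt, from 0.555% to 23.0% in Lmna +/+ and from 1.21% to 18.2% in Lmna F/F. With Uprt it ranged from 0.843% to 7.59% in Lmna +/+ and from 0.884% to 3.62% in Lmna F/F. Loci with higher odds are called Uprt-labelled here. Called from Lmna +/+ mice alone, with 3 mice without Uprt, their number was 3415 of 10199 (33.5%), of which 3366 were among the 7038.

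In total RNA of mice with Uprt, more loci were higher than lower in Lmna F/F. All reads were higher in Lmna F/F than in +/+ at 727 of 20523 loci (3.54%) and lower at 174 (0.848%). Among the loci that rose the median log2 fold change was 1.13, and 427 rose by at least 1 on the log2 scale; among those that fell the median was -0.48, and 17 fell by at least 1. ENSMUST00000030056.12, whose most read interval lies on chromosome 4 from 63878022 to 63878669, rose from 0.411 ± 0.177 CPM (SD, n = 8) to 9.73 ± 5.22 CPM (SD, n = 6), a log2 fold change of 4.57 ± 0.60 (SE, edgeR adjusted p = 5.83e-05). ENSMUST00000192926.2, on chromosome 3 from 63388533 to 63388614, fell from 241 ± 76.1 to 56.0 ± 15.1 CPM, a log2 fold change of -2.01 ± 0.22 (SE, edgeR adjusted p = 9.06e-06).

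At both loci the ranges of the 2 genotypes did not overlap. ENSMUST00000054599.8, on chromosome 3 from 92391259 to 92391564, had 8 reads in all 8 Lmna +/+ libraries together and 310 in the 6 Lmna F/F libraries, with a log2 fold change of 5.28 ± 0.76 (SE, edgeR adjusted p = 0.000138). ENSMUST00000230340.2, on chromosome 15 from 78416824 to 78416997, had a log2 fold change of -1.66 ± 0.44 (SE, edgeR adjusted p = 0.0316). It was not called without Lmna F/F Uprt replicates 1, 2, 3 or 5 (-1.59, -1.64, -1.59 and -1.62) or without Lmna +/+ Uprt replicates 1, 4, 6 or 8 (-1.45, -1.61, -1.63 and -1.60). In mice without Uprt its log2 fold change was 0.03 ± 0.60 (SE, edgeR adjusted p = 0.985).

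The count of 901 fell to 520, 508 and 599 without Lmna F/F Uprt replicates 1, 2 and 3 respectively, and DESeq2 called 1380 loci. Without chromosome 3, to which Lmna is assigned, it was 844, with 688 higher and 156 lower. ENSMUST00000192926.2 and ENSMUST00000054599.8 lie on that chromosome. Loci close to Lmna could not be set apart, so whether these changes go with the position of the floxed allele was not tested. Scaled by library size alone instead of by TMM, the median of all loci moved to 0.16 on the log2 scale, 1419 loci were called higher and 25 lower.

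In mice without Uprt, which are other animals tested in the same fit of all 21 libraries, 1112 loci were higher in Lmna F/F and 716 lower. ENSMUST00000030056.12 rose there too, by 7.34 ± 1.02 on the log2 scale (SE, edgeR adjusted p = 0.000289), from 0.328 ± 0.0443 CPM (SD, n = 3) to 45.9 ± 46.4 CPM (SD, n = 4), with 1.49 to 90.1 CPM in single Lmna F/F mice. The rise was 4.32 without Lmna F/F no Uprt replicates 1 and 2 together, and it was not called in the 7 libraries alone (7.24, edgeR adjusted p = 0.105). ENSMUST00000192926.2 fell by 2.06, from 412 ± 160 CPM (SD, n = 3) to 84.2 ± 32.5 CPM (SD, n = 4). ENSMUST00000054599.8 rose by 7.02 ± 1.16 (SE, edgeR adjusted p = 0.000776). It had 4 reads over 3 Lmna +/+ libraries, 2 of them at 0, and 755 reads over 4 Lmna F/F libraries, which held 0.171 to 9.34 CPM each. A locus on chromosome 5 from 104588485 to 104588916 went from 10 reads over 3 Lmna +/+ libraries to 3189 reads over 4 Lmna F/F libraries, which held 1.37 to 42.5 CPM each; it was not called without Lmna F/F no Uprt replicates 1 and 2 together (4.48) or in the 7 libraries alone (7.63). Both loci with the largest falls differed between the Lmna +/+ mice themselves: one on chromosome 13 from 73465963 to 73466262, with a log2 fold change of -4.83 ± 0.89 (SE, edgeR adjusted p = 0.00159) and one on chromosome 17 from 36427089 to 36428013, with -4.92 ± 1.09 (SE, edgeR adjusted p = 0.00644). Without Lmna +/+ no Uprt replicate 2 these log2 fold changes were 0.03 and -1.63, and neither was called. Across both comparisons 490 loci were higher in both and 76 lower in both, against 39.4 and 6.07 for independent lists, and 0 were called in opposite directions, against 25.4 and 9.43. Across the 20523 loci, which are not independent replicates, the log2 fold changes had a Pearson r of 0.529.

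These counts without Uprt rest on few mice. The 4 Lmna F/F libraries were uneven, and the count of 1828 loci was 544 without replicate 1 of that group, 1099 without its replicate 2 and 144 without both. It was 863, 973 and 1051 without Lmna +/+ no Uprt replicates 1, 2 and 3, and 5 when only the 7 libraries of these mice entered the fit; of the 35 ways to split the 7 mice into 4 and 3, another called 2577. Scaled by library size alone, the median moved to 0.18 and the split was 1528 higher and 319 lower.

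The Lmna effect was also compared between mice with and without Uprt directly. edgeR's interaction test called 0 of 20523 loci, with 1743 at an unadjusted p under 0.05, and DESeq2 called 5. At loci called with Uprt, the log2 fold change without Uprt was larger by a median factor of 1.22, and 97.6% of these loci had the same sign. At loci called without Uprt, the log2 fold change with Uprt was a median of 0.435 of that without, and 96.5% had the same sign. The size of the ratio thus depends on which calls select the loci.

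**Figure D2:**
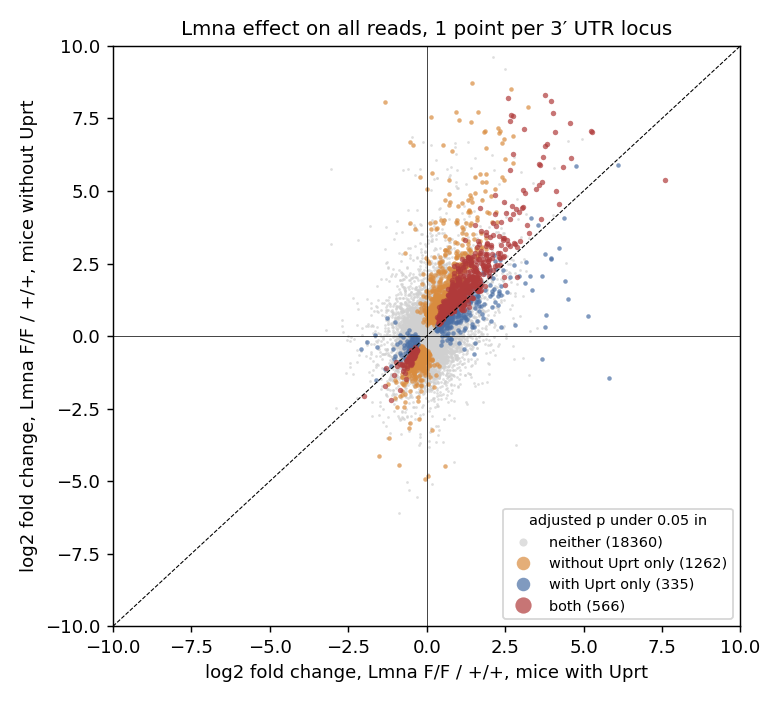
Log2 fold change of all reads, Lmna F/F over +/+, in mice with Uprt (horizontal) and without Uprt (vertical), with 1 point per 3′ UTR locus, coloured by the comparisons in which its adjusted p was under 0.05; the dashed line marks equal values. The 490 loci called higher in both comparisons lie at the upper right and the 76 called lower in both at the lower left.

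Loci that rose with Lmna F/F were seldom among the Uprt-labelled ones. With Uprt, 120 of the 475 risen loci that could be tested for labelling were labelled (25.3%), against 60.4% of the other loci (odds ratio 0.222, 95% interval 0.178 to 0.275, Fisher's exact p = 4.60e-52). Loci that fell were labelled more often, 118 of 161 (73.3%) against 58.8% of the others (odds ratio 1.93, 95% interval 1.34 to 2.80, Fisher's exact p = 0.000188). Without Uprt, 27.7% of 740 risen loci and 75.8% of 658 fallen loci were labelled. The median log2 odds ratio of a T>C read, Uprt against none, was 0.49 at the loci that rose with Uprt and 1.17 at loci not called. Over 10 strata of mean CPM the Mantel-Haenszel odds ratio was 0.209 for risen loci (95% interval 0.167 to 0.260) and 1.30 for fallen loci (0.906 to 1.87). With labelled loci called from Lmna +/+ mice alone, 19.2% of risen loci were labelled against 33.9% of the others, an odds ratio of 0.463 (0.338 to 0.623) and a Mantel-Haenszel odds ratio of 0.404 (0.300 to 0.544). For fallen loci it was 1.85 (1.33 to 2.58) with labelled loci called from Lmna +/+ mice alone, and without Uprt it was 1.42 (1.18 to 1.72) and 1.29 (1.09 to 1.53) with labelled loci from all mice and from Lmna +/+ mice, so 3 of the 4 intervals lay above 1. Loci are not independent replicates, and these tests measure association over loci.

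**Figure D3:**
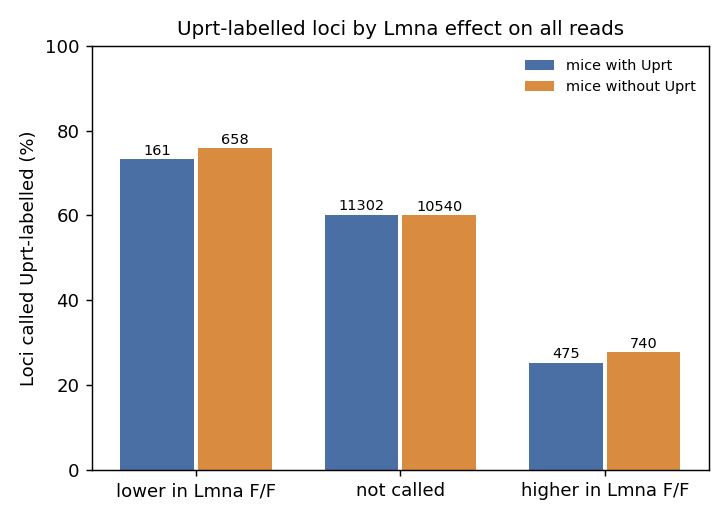
Percent of loci called Uprt-labelled among loci whose all-read level was lower, not called or higher in Lmna F/F, in mice with and without Uprt; the number over each bar is the number of loci. The share is 25.3% and 27.7% among risen loci, and 60.2% and 60.1% among loci not called.

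The comparison the labelling was built for is that of T>C reads alone between Lmna genotypes in mice with Uprt. Of 9659 loci, 46 had more T>C reads in Lmna F/F, with a median log2 fold change of 1.58, and 5 had fewer. All reads were also higher at 39 of the 46, of which T>C reads are a part. The largest rise was at a chromosome 14 locus from 47623138 to 47623617, from 2.83 ± 2.74 T>C CPM (SD, n = 8) to 47.1 ± 31.9 (SD, n = 6), a log2 fold change of 4.21 ± 0.53 (SE, edgeR adjusted p = 0.000263). A locus on chromosome X from 20740872 to 20740974 rose by 3.97 ± 0.43 (SE, edgeR adjusted p = 0.000145). ENSMUST00000192926.2 was among the 5 and fell by 2.33 on the log2 scale (edgeR adjusted p = 0.00106). None of these 3 loci was called Uprt-labelled: the log2 odds ratios of a T>C read, Uprt against none, were -0.10, -0.70 and -0.06 (edgeR adjusted p = 0.902, 0.0681 and 0.812). Of the 46 loci with more T>C reads, 15 were Uprt-labelled (32.6%), against 68.1% of the other loci (odds ratio 0.226, 95% interval 0.113 to 0.433, Fisher's exact p = 1.30e-06).

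At the 304 loci whose all reads rose and that were tested in both, T>C reads went the same way at 293, with medians of 0.80 in all reads and 0.82 in T>C reads. T>C reads are a part of the reads that picked these loci and include background, so this need not reflect newly made RNA. Of the 5 loci with fewer T>C reads, 3 had a T>C share of over 20% in a mouse without Uprt and no change called in all reads, namely those on chromosome 9 from 37449079 to 37449615, on chromosome 15 from 78043663 to 78043809 and on chromosome 3 from 96128863 to 96131054. The chromosome 9 locus was not called without Lmna F/F Uprt replicate 5 (-3.74), nor the chromosome 15 locus without Lmna F/F Uprt replicates 1, 2, 3, 4, 5 or 6 (-4.44, -4.16, -4.53, -3.96, -3.93 and -4.21). Of the 46 loci with more T>C reads, 9 also reached a T>C share of 20% in a mouse without Uprt. DESeq2 called 99 loci, and 15 were called when only Uprt-labelled loci were tested. No locus differed in its Lmna effect on T>C reads between females and males (0 of 9659 by edgeR, 485 at an unadjusted p under 0.05, 1 by DESeq2), although the same test on simulated counts recovered 0 of 200 loci changed by 1 on the log2 scale.

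Mice without Uprt give the background for this measure. Of 7552 loci, 3 had more T>C reads in Lmna F/F and 0 had fewer, with 640 at an unadjusted p under 0.05 by edgeR and 84 called by DESeq2. The chromosome 14 locus above was one of the 3, with a log2 fold change of 5.92 ± 0.57 (SE, edgeR adjusted p = 0.00966), so its T>C reads rose with Lmna F/F where no transgene was present, although it was not called without Lmna +/+ no Uprt replicate 3 (5.54). A locus on chromosome 11 from 82007461 to 82007625 rose by 4.92 ± 0.59 (SE, edgeR adjusted p = 0.0228), and was not called without Lmna F/F no Uprt replicate 1 (4.10) or Lmna +/+ no Uprt replicates 1, 2 or 3 (4.89, 4.80 and 5.004). In simulated counts of this size 0 of 200 loci changed by 1 on the log2 scale were recovered, and the count was 9, 11, 16 and 12 without Lmna F/F no Uprt replicates 1, 2, 3 and 4, and 7 and 1 without Lmna +/+ no Uprt replicates 1 and 3.

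The share of T>C reads at a locus, apart from its total, was called changed at 3 of 9659 loci. The share rose in Lmna F/F at a pair of adjoining loci on chromosome 2, at 13587284 to 13587289 and at 13587295 to 13587636, with log2 odds ratios of 3.36 ± 0.52 and 3.28 ± 0.52 (SE, edgeR adjusted p = 0.0148 and 0.0159). At the first of them 53.1% ± 4.22 of reads carried a conversion in Lmna F/F with Uprt (SD, n = 6) and 14.4% ± 19.6 in Lmna +/+ with Uprt (SD, n = 8). Without Uprt it was 49.3% ± 10.9 in Lmna F/F (SD, n = 4), and Lmna +/+ replicate 1 of both transgene groups stood at 62.8% and 68.9%. T>C reads at the first and second chromosome 2 locus were similar, from 7107 and 7077 in Lmna F/F Uprt replicate 1 to 783 and 556 in Lmna +/+ Uprt replicate 8. The adjoining loci may hold the same reads, so their 2 calls are not separate evidence. The share fell at a locus on chromosome 11 from 94842446 to 94843868, from 22.9% ± 3.28 to 10.9% ± 1.90, a log2 odds ratio of -1.23 ± 0.16 (SE, edgeR adjusted p = 0.00285). All 3 loci have a T>C share of over 20% in a mouse without Uprt, and without such loci 0 of 8950 were called, with 330 at an unadjusted p under 0.05. In the main comparison 370 loci had an unadjusted p under 0.05, and the quasi-binomial model called 1. The count was 1 without Lmna F/F Uprt replicate 1 or 5 or Lmna +/+ Uprt replicate 7 or 8. The first chromosome 2 locus was also not called without Lmna +/+ Uprt replicate 3 (3.21), nor the second without that library (3.19) or Lmna F/F Uprt replicate 3 (3.25).

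**Figure D4:**
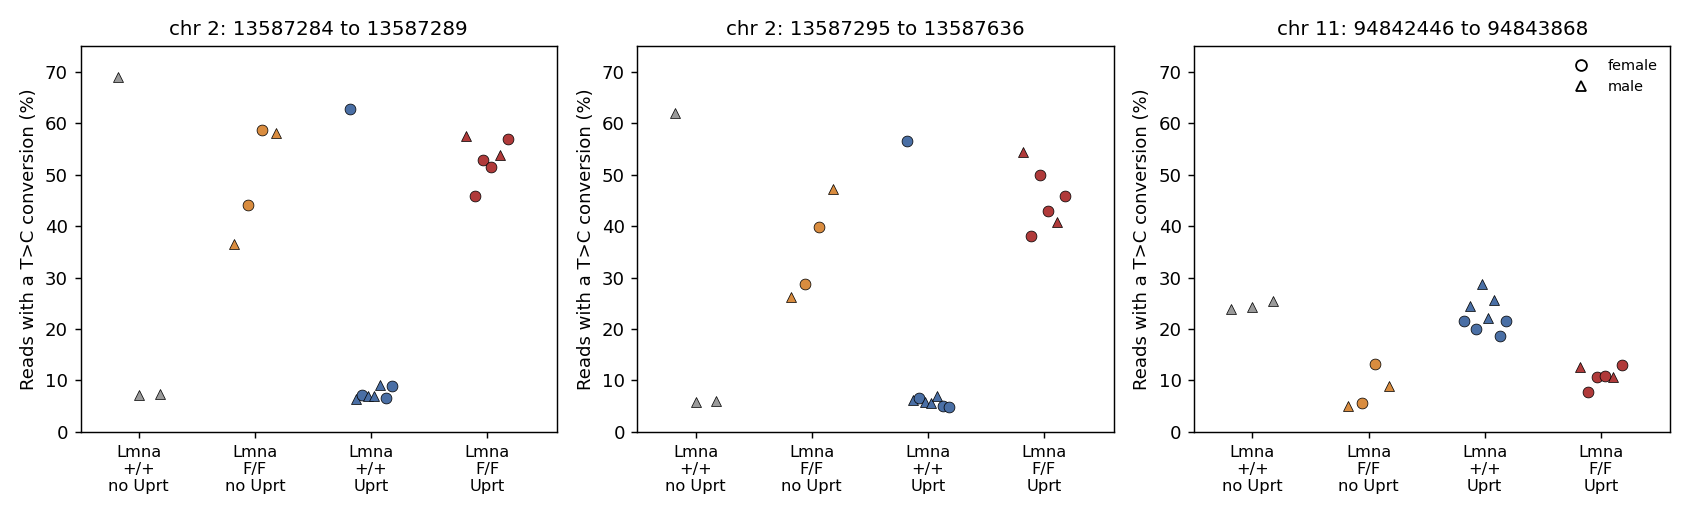
Percent of reads with a T>C conversion in each library at the 3 loci with a called difference between Lmna F/F and +/+ with Uprt, by group; circles are females and triangles males, and positions are on mm39. At the chromosome 2 loci the Lmna F/F mice lie at 26.2% or above with and without Uprt, as does 1 Lmna +/+ mouse of each transgene group.

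Few loci were called between mice with and without Uprt in all reads. By edgeR 19 of 20523 loci were higher with Uprt and 6 lower, with 2098 at an unadjusted p under 0.05, and DESeq2 called 142. Chromosome 17 held 6 of the 25 called loci, against 904 of the loci tested (Fisher's exact p = 0.000619, adjusted p = 0.0136 over 22 chromosomes). Of these, a locus from 36427089 to 36428013 had a log2 fold change of 5.11 ± 0.58 (SE, edgeR adjusted p = 8.52e-05), with 2.88 ± 0.652 CPM in Lmna +/+ with Uprt (SD, n = 8) and 2.72 ± 0.913 in Lmna F/F with Uprt (SD, n = 6). Without Uprt it held 0.0125 ± 0.0250 CPM in Lmna F/F (SD, n = 4), and 0.0274, 1.39 and 0.0632 CPM in Lmna +/+ replicates 1, 2 and 3. Another from 34534862 to 34535648 fell by 1.65 on the log2 scale (edgeR adjusted p = 0.00114). Called loci from 35978722 (-0.93) and 36348325 (2.42) lie near them, while those from 6187486 (0.43) and 57058325 (0.65) lie farther off. Fisher's test treats such neighbours as independent, so its p-value can overstate the excess on this chromosome. The count of 25 was 16, 16 and 44 without Lmna F/F Uprt replicates 2, 3 and 5, 13 and 15 without Lmna +/+ Uprt replicates 4 and 6, 12 and 41 without Lmna F/F no Uprt replicates 2 and 4, and 11, 10 and 11 without Lmna +/+ no Uprt replicates 1, 2 and 3. By library size alone the median moved to -0.13, with 7 loci higher and 13 lower.

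Females and males differed at 27 loci, 10 higher and 17 lower in females. Of the 8 Y chromosome loci tested 5 were called lower in females, and 3 of the 10 higher ones lay on the X chromosome. Reads on the Y chromosome that mapped to 1 place came to 4.12 to 6.33 CPM of the library's reads on loci in the 10 females and 115 to 192 CPM in the 11 males, so every library matched its labelled sex. The count of 27 was 215, 283, 11 and 12 without Lmna F/F no Uprt replicates 1, 2, 3 and 4, it was 15, 14 and 10 without Lmna F/F Uprt replicates 4, 5 and 6, and it was 13, 11, 10, 12, 11 and 12 without Lmna +/+ Uprt replicates 1, 2, 4, 6, 7 and 8. DESeq2 called 250. By library size alone 15 loci were higher and 10 lower.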

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

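Tests chosen only after the result was seen are that of cells that do not express Uprt or slow turnover, those of the loci on chromosomes 2 and 11, and that of an Lmna effect that depends on Uprt; the others in this part were chosen before.

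Loci that rose with Lmna F/F were seldom Uprt-labelled, 25.3% against 60.4% of the other loci. Their mean expression level over all libraries as the whole cause is argued against by the Mantel-Haenszel odds ratio over strata of CPM, whose 95% interval ends at 0.260. These strata include the Lmna F/F mice, where the risen loci are higher, so the level in Lmna +/+ mice alone was not matched. Calling labelled loci from Lmna +/+ mice alone gave a weaker odds ratio of 0.463, whose interval stayed below 1 with an upper bound of 0.623. The median log2 odds ratio of a T>C read at the risen loci was 0.49, which RNA of cells that do not express Uprt and RNA that turns over slowly may both give, and with 1 labelling time these cannot be told apart.

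The T>C share differed between Lmna genotypes with Uprt at 3 loci. Over both chromosome 2 loci, which may hold the same reads, the mean share in Lmna F/F mice without Uprt was 0.862 of that with Uprt. At neither locus was the share below 26.2% in such a mouse, which argues against labelling through Uprt as the cause. A sequence variant read as a conversion is a candidate explanation that these values fit, and no sequence was available to test it directly. At the chromosome 11 locus T>C reads changed by 0.0321 ± 0.317 (SE) on the log2 scale without Uprt while all reads rose by 1.78 ± 0.31 (SE), so a second source of T>C reads that did not change may account for the lower share.

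More loci were called for Lmna F/F without Uprt than with it in the fit of all 21 libraries, 1828 against 901. With each set of mice fitted alone, 5 were called in the 7 libraries without Uprt and 1369 in the 14 with Uprt. The order thus depends on which libraries share the fit. A single library could account for the excess in the shared fit in part. The count without Uprt was 544, 1099, 2671 and 2432 without Lmna F/F no Uprt replicates 1, 2, 3 and 4. It was 863, 973 and 1051 without Lmna +/+ no Uprt replicates 1, 2 and 3. In the same refits the count with Uprt was 1041, 1079, 1043 and 995, and 775, 790 and 785. The order thus turned only without Lmna F/F no Uprt replicate 1. The count of 901 itself fell to 520, 508 and 599 without Lmna F/F Uprt replicates 1, 2 and 3. The absence of females among Lmna +/+ mice without Uprt stays open, since the median ratio of the log2 fold changes, without over with Uprt, was 1.24 among males and ranged from 0.831 to 1.54 with each of 11 males left out. An Lmna effect that depends on Uprt stays open too, since edgeR called 0 loci for it, with 1743 at an unadjusted p under 0.05 and 5 by DESeq2, and the same test recovered 22.0% of simulated changes.

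Single libraries stood apart from the rest of their group in 7 of 66 groups of values tested. The nominal rate of about 1 in 20 need not hold here, since the groups include loci chosen for large changes and some hold few reads. The percent of reads with a T>C conversion was 5.92 in Lmna +/+ Uprt replicate 3, the next highest 5.17. The chromosome 5 locus from 104588485 had 2.10 CPM in Lmna +/+ Uprt replicate 7, the next highest 0.252. The chromosome 17 locus from 36427089 had 0.0499 CPM in Lmna F/F no Uprt replicate 2 and 0 in the other 3 mice, a difference of only 2 reads. The chromosome 10 locus from 111134540 had a T>C share of 37.5% in Lmna F/F Uprt replicate 1, the next highest 10.6%. The chromosome 19 locus from 21914744 had 7.59% in Lmna +/+ Uprt replicate 5, the next highest 1.63%. The chromosome 2 loci, which may hold the same reads, had 62.8% and 56.5% in Lmna +/+ Uprt replicate 1, the next highest 9.05% and 6.99%. Females held up to 221 Y chromosome reads that mapped to 1 place, and males at least 4024.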

How the results depend on the processing

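Tests chosen only after the data were seen are those by library size alone, on mitochondrial or nuclear loci alone, without chromosome 3, without mitochondrial loci and the most abundant nuclear locus, without loci that reach a T>C share of 20% in a mouse without Uprt, and without Lmna F/F no Uprt replicates 1 and 2 together. Of 321 alternatives for counts and library shares, 234 kept direction and call or stayed within 1.5 times the count. For 21 values of named loci, 490 of 538 alternatives did so, 47 lost the call and 1 turned: the chromosome 13 locus from 73465963 went to 0.0344 without Lmna +/+ no Uprt replicate 2, in a range from -5.40 with 1 library left out. For the changes given here the cause was not tested.

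For Lmna F/F against +/+ in all reads with Uprt, the count of 901 was 1678 without the low-count filter, 1380 by DESeq2, 1444 by library size alone, 395 in females only and 1369 with the 14 libraries alone. With 1 library left out it ranged from 508 to 1079: 520, 508 and 599 without Lmna F/F Uprt replicates 1, 2 and 3. Without Uprt the 1828 became 144 without Lmna F/F no Uprt replicates 1 and 2 together, 5 with the 7 libraries alone and 536 in males only. With 1 library left out it ranged from 544 to 2671, with 544 and 1099 without Lmna F/F no Uprt replicates 1 and 2, and 863, 973 and 1051 without Lmna +/+ no Uprt replicates 1, 2 and 3, while it was 2671 and 2432 without Lmna F/F no Uprt replicates 3 and 4. The interaction count of 0 by edgeR (1743 at an unadjusted p under 0.05) was 345 without the filter, 5 by DESeq2 and 0 to 4 with 1 library left out: 2 and 1 without Lmna +/+ Uprt replicates 1 and 2, 1 and 4 without Lmna +/+ no Uprt replicates 1 and 3, and 1 without Lmna F/F no Uprt replicate 3.

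For Uprt against none, 25 became 393 without the filter and 142 by DESeq2, and 10 to 44 with 1 library left out: 16, 16 and 44 without Lmna F/F Uprt replicates 2, 3 and 5, 13 and 15 without Lmna +/+ Uprt replicates 4 and 6, 12 and 41 without Lmna F/F no Uprt replicates 2 and 4, and 11, 10 and 11 without Lmna +/+ no Uprt replicates 1, 2 and 3. For sex, 27 became 598 without the filter and 250 by DESeq2, and 10 to 283 with 1 library left out: 215, 283, 11 and 12 without Lmna F/F no Uprt replicates 1, 2, 3 and 4, 15, 14 and 10 without Lmna F/F Uprt replicates 4, 5 and 6, and 13, 11, 10, 12, 11 and 12 without Lmna +/+ Uprt replicates 1, 2, 4, 6, 7 and 8.

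For T>C reads with Uprt, 51 became 184 without the filter, 99 by DESeq2, 15 among Uprt-labelled loci only and 22 in females only, and 39 to 57 with 1 library left out. Without Uprt, 3 became 255 without the filter, 84 by DESeq2, 5 with no sex term, 6 without loci that reach a share of 20%, and 1 to 16 with 1 library left out: 9, 11, 16 and 12 without Lmna F/F no Uprt replicates 1, 2, 3 and 4, and 7 and 1 without Lmna +/+ no Uprt replicates 1 and 3. The interaction with sex, 0 by edgeR (485 at an unadjusted p under 0.05), was 87 without the filter, 1 by DESeq2, and 0 to 2 with 1 library left out, with 2 without Lmna F/F Uprt replicate 5 or Lmna +/+ Uprt replicate 5; by library size alone its median moved to -0.17.

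For the T>C share of a locus, Uprt against none, 7063 became 3421 in Lmna +/+ alone. For Lmna F/F against +/+, 3 became 47 without the filter, 1 in the quasi-binomial model, 0 without loci that reach a share of 20% (330 at an unadjusted p under 0.05) and 0 among Uprt-labelled loci only (233), and 1 to 4 with 1 library left out: 1 without Lmna F/F Uprt replicates 1 or 5 or Lmna +/+ Uprt replicates 7 or 8. For the library share, mitochondrial loci only gave 0.00276 and 0.661 points for Uprt within Lmna +/+ and F/F, and -0.191 and -0.850 points for Lmna F/F against +/+ with and without Uprt. Within Lmna +/+ males only gave 1.21, and leaving out 1 library gave 1.10 to 1.48: 1.10, 1.48 and 1.46 without Lmna +/+ no Uprt replicates 1, 2 and 3, where 8 against 2 mice cannot pass the adjusted threshold. For Lmna F/F against +/+ without Uprt it ranged from -0.204 to 0.172, with -0.204 without Lmna +/+ no Uprt replicate 1 and -0.120 without Lmna F/F no Uprt replicate 4.

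No paired analysis was possible because the labels give no number shared by mice; blocks by runs of title numbers were not fitted. Not run, for want of gene names, were the gene lists, their test with an estimated correlation, the level of Lmna and the exclusion of loci close to Lmna. In T>C reads 9659 loci passed the low-count filter with Uprt and 7552 without.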

Other observations

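Tests chosen only after the result was seen are those of the score, of mitochondrial loci and of the mouse without Uprt; the splits of the mice were chosen before.

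As a set, the 1828 loci called without Uprt had a mean score that differed between Lmna genotypes in mice with Uprt, which shared the fit that called them, although only 490 were called higher and 76 lower there. This score was -2.09 ± 0.189 in Lmna F/F with Uprt (SD, n = 6) and -3.00 ± 0.124 in Lmna +/+ with Uprt (SD, n = 8), with an exact permutation p of 0.000666, the smallest possible. A fit of the 7 libraries without Uprt alone gave 1879 higher and 1159 lower loci at an unadjusted p under 0.05, of 18698. The score of these loci was -1.51 ± 0.131 in Lmna F/F with Uprt (SD, n = 6) and -2.26 ± 0.104 in Lmna +/+ with Uprt (SD, n = 8), again with the smallest exact permutation p, 0.000666. Among Lmna F/F mice without Uprt, replicates 1 and 2 had scores of -0.58 and -0.76 and replicates 3 and 4 of -2.32 and -1.86, on loci called from these same mice. The sample titles carry a number for each mouse whose meaning is not given in the sources used here; replicates 1 and 2 are neighbours in it, as are replicates 3 and 4, and most mice with Uprt have lower numbers than every mouse without it. Whether the numbers follow litters or days was not tested.

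All 15 mitochondrial loci tested had a log2 fold change below 0 in Lmna F/F with Uprt, with a median of -0.33 and 1 called; by library size alone 14 were below 0, with a median of -0.16, 0 called by edgeR, and a median of all loci of 0.16. Mitochondrial loci took 28.2% ± 2.52 of reads in Lmna F/F with Uprt (SD, n = 6) and 30.1% ± 1.86 in Lmna +/+ with Uprt (SD, n = 8, exact permutation p = 0.155), and 27.7% ± 1.41 against 27.2% ± 0.875 without Uprt (SD, n = 4 and 3, exact permutation p = 0.743), which leaves open whether their share of reads was smaller. Whether mitochondrial RNA takes up label through Uprt stays open as well: the larger exact permutation p for its T>C share was 0.982, in Lmna +/+ (n = 8 and 3), whereas by locus the T>C odds were above 0 on the log2 scale at 14 of 14 mitochondrial loci and called higher at 12, with a median of 0.67.

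A pair of loci were high in mice with Uprt and in Lmna +/+ no Uprt replicate 2. The chromosome 13 locus from 73465963 had 128 to 185 CPM in the 14 mice with Uprt, 154 in this mouse and 1.42 to 2.15 in the other 6 without Uprt. Over all libraries 23.1% of its reads were multimapped, so not all of them need come from this position. A mouse with Uprt that was labelled as without it is argued against by its T>C share on nuclear loci of 3.48%, below the lowest share with Uprt, 4.52%, and within the 2.68% to 3.85% of the other mice without Uprt. Whether these loci are linked to the transgene site was not tested.

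Splits of the same mice into groups of these sizes were fitted the same way, and the counts of splits include the real one. No other split called as many for the 901 loci of Lmna F/F with Uprt (1 of 100 splits, highest other 159) or the 51 loci of T>C reads with Uprt (1 of 100, highest other 5). Nor did any for the 7063 loci of the T>C share with Uprt against none, where only 30 splits were fitted (1 of 30, highest other 0). Other splits called at least as many loci for Uprt against none (25 loci, 2 of 100, highest other 141) and for sex (27 loci, 3 of 100, highest other 318). The same held for the T>C share between Lmna genotypes (3 loci, 3 of 100, highest other 3). Chance is not excluded there, and no count of splits given here is adjusted over the comparisons, those of 1 split included. For Uprt and for sex another split called several times as many, which points to a structure of the samples; what these splits follow was not tested. The splits do not exclude chance for the 3 loci of T>C reads without Uprt (12 of 35, highest other 39). Nor do they by themselves for the 1828 loci of Lmna F/F without Uprt (2 of 35, highest other 2577), although the loci ranked in the 7 libraries alone separated the genotypes in mice with Uprt (exact permutation p = 0.000666). Where edgeR called 0 loci, every split calls as many, so the splits decide nothing for the interaction with Uprt (100 of 100, highest other 313; 1743 at an unadjusted p under 0.05, 5 by DESeq2) or with sex (100 of 100, highest other 9; 485 and 1). The split that called 2577 set Lmna F/F no Uprt replicates 1, 2 and 4 against the other 4 mice, so it differs from the genotypes in replicate 3 of that group alone.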
